A study of Mus musculus with 6 samples.

How the data were processed

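RNA from 6 cultures or culture samples of primary mouse renal tubular epithelial cells was sequenced after mRNA enrichment, per the labels' protocols. Groups were taken from the sample titles, with 3 control and 3 knockout libraries. The submitters' processing notes name featureCounts, Salmon and the mm10 build, without versions or roles. The estimated counts were deposited by the authors as read counts per gene without normalisation or scaling. Of its nonzero values 93.3% were whole within 1e-06, and 2063 genes had a fractional value in at least 1 library, as reads divided between genes would give. A second deposited table held TPM, normalised by the authors to the same sum in each library. Strand setting, annotation release and read filters are not given in the sources used here.

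Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr on the 2 groups, which kept 13755 of 55487, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. Means and SDs are of TMM-normalised CPM over 3 libraries. The biological coefficient of variation was 5.35%. Total estimated counts lay between 8961779 and 10774195, and intervals and floors cover counting error only. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom of 2.03 to 3.67, which does not show whether they are separate cultures.

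Before the data were examined, 34 gene lists were fixed for the cytokine responses, nephron segments, other cell types, cell states and metabolism. Each was tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), adjusted over the 34 lists, and an estimated correlation and fry served as alternatives. Counts per list are over all genes tested, beside counts adjusted over the list alone. The test and the median, or the median and the mean, differed in sign for the lists of NF-κB and TNF response, ELF3-linked genes, ETS family, collecting duct, MHC class II and oxidative phosphorylation. Lists share members.

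Named genes followed a rule also fixed beforehand: Elf3, the 10 largest rises and 10 largest falls and the 3 smallest p-values per direction among called genes with at least 5 CPM in the higher group and no overlap between groups, leaving out unnamed gene models and pseudogenes, and up to 4 called members with the smallest p-values in each list, or 2 where none was called. The text gives a part of the 138 genes so chosen. Exons of 22 of them overlap exons of another tested gene in GENCODE M21. These include Spp1, Fbn1, Ltbp2, Csf1r and Ccdc152, whose counts may hold reads of the neighbour. Positions are from GENCODE M21 on mm10, which held 55227 of the 55487 gene identifiers.

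The main edgeR model, DESeq2, limma-voom and limma on log2(CPM + 1) were first tested on simulated counts for 13755 genes. The design was 3 against 3 libraries, with 200 changed genes. The other alternatives listed below were not simulated. edgeR recovered 44% of 1.25-fold, 70% of 1.5-fold, 88% of 2-fold and 96% of 4-fold changes. In the data 36.6% of tested genes were called, a far larger share than was changed in the simulation. The adjusted threshold depends on that share, so these rates need not hold for the data. For 2-fold changes recovery was 97.4% at 5 CPM or more (38 of 39 genes) and 54.5% below (6 of 11). The share below rests on few genes, but changes in low genes can be missed. Of 500 random unshifted lists of 30 genes, 0% had a camera p and 4.4% a fry p under 0.05. Simulated genes were drawn independently, so these shares do not cover lists whose genes vary together.

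Alternatives were RLE size factors, library totals, DESeq2 1.42.0, limma-voom, no count filter, a mean of at least 5 CPM, the replicate number as a block, log2(TPM + 1) and log2(TPM + 0.1) with limma at a mean TPM of at least 0.5, log2(TPM + 1) without a filter, an adjusted p under 0.01, and leaving out each library. A loess offset for GC content and transcript length was added after seeing the data. Fold changes on TPM are on the log2(TPM + pseudocount) scale, which understates the change of low genes. Nuclear copies of mitochondrial genes were found with blastn 2.17.0 at 95% identity or more over at least 80% of the length.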

Results

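Gene expression was measured by bulk RNA sequencing in primary epithelial cells cultured from mouse kidney tubules. The 6 libraries formed 2 groups of 3. One group had received an adenovirus carrying Cre recombinase, labelled as inducing deletion of the epithelial ETS transcription factor gene Elf3, and is called the knockout here. The other had received a control adenovirus. All 6 carried labels of exposure to the cytokines TNFα and IFNγ and of the same batch. Total estimated counts per library ranged from 8961779 to 10774195, and a floor of 3 counts corresponded to between 0.278 and 0.335 CPM (counts scaled to a common library size), which covers counting error only. Libraries of 1 group correlated at r = 0.989 to 0.991 over log2 CPM, and libraries of different groups at 0.967 to 0.971, across genes, which are not independent replicates.

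**Figure D1:**
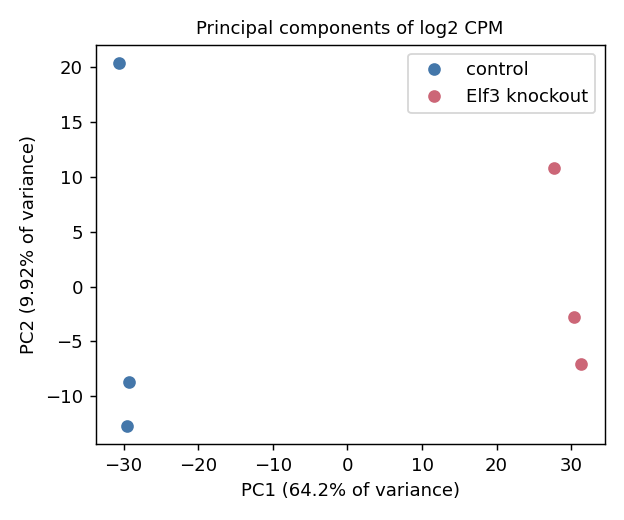
Principal components of log2 CPM over 13755 genes, with PC1 on the horizontal and PC2 on the vertical axis, in component units, and 1 point per library. The first component, with 64.2% of the variance, separates the 3 control from the 3 knockout libraries.

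Elf3 (ENSMUSG00000003051, mm10 chromosome 1, 135253575 to 135258568, minus strand) was lower in each knockout library than in each control. Its level was 22 ± 2.76 CPM in the controls and 3.10 ± 1.12 CPM in the knockout (SD, n = 3 each), so that 14.1% of the control level was counted. Estimated counts were 201, 250 and 206 in the controls and 38, 32 and 21 in the knockout libraries. The log2 fold change was -2.84 (adjusted p = 6.84e-14, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). A two-sided exact permutation test of log2 CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. The part of the gene removed by Cre is not given in the sources used here, so the counts cover the gene as a whole.

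The comparison of knockout with control asks which transcripts differ when Elf3 is deleted in tubular cells labelled as exposed to both cytokines. Transcripts of Clca3b, a member of the calcium-activated chloride channel regulator family, were among those that fell furthest, from 142 ± 5.92 to 11.6 ± 1.70 CPM. The neutrophil-attracting chemokine Cxcl5 fell 7.75-fold, and the iron-sequestering protein Lcn2, a marker of kidney injury, fell 4.78-fold. The matrix metalloproteinase Mmp9 rose 6.57-fold, from 17.4 ± 1.18 CPM in the controls, and the sphingosine 1-phosphate receptor S1pr3 rose 12.3-fold. Of 13755 genes tested, 2516 were higher and 2512 lower in the knockout at an adjusted p under 0.05. By 2-fold or more, 411 were higher and 420 lower. The groups did not overlap for 46.7% of all tested genes, where chance gives 10% for 3 against 3, and for 95.1% of the called genes, which the same values selected.

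**Figure D2:**
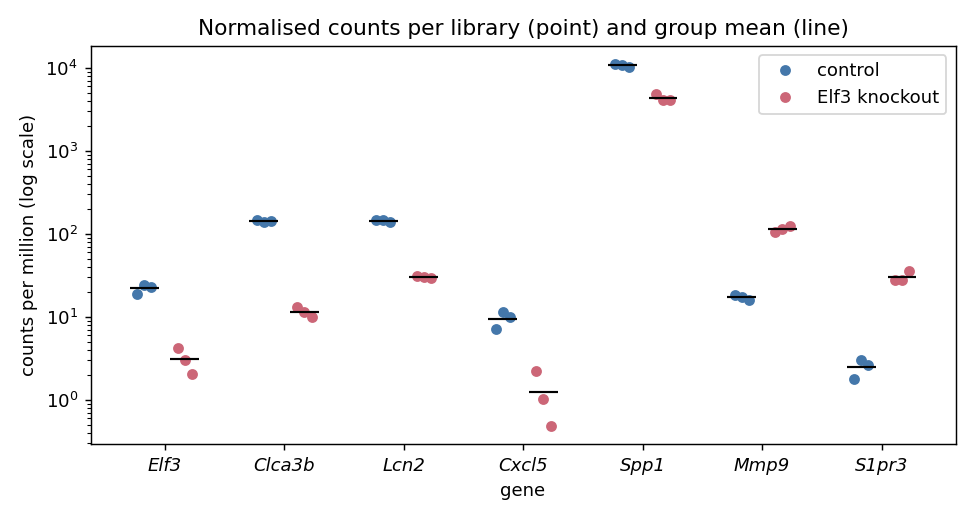
Normalised CPM, on a log axis, for 7 genes in the 3 control and 3 knockout libraries, 1 point per library, with a line at each group mean. Elf3, Clca3b, Lcn2, Cxcl5 and Spp1 lie lower in all 3 knockout libraries, and Mmp9 and S1pr3 higher.

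Among the genes with large falls and at least 5 CPM in the controls was Ugt2b34, a UDP-glucuronosyltransferase, at 14.4 ± 2.76 CPM in the controls and 0.565 ± 0.492 in the knockout. The potassium channel gene Kcnj16 fell 8.18-fold. Cyp2j5, a kidney cytochrome P450, fell 8.08-fold and Sprr1a, a cornified envelope protein, 7.71-fold. Apela, a ligand of the apelin receptor, had 157 counts over the controls and 1 over the knockout libraries, a ratio of 157 (95% exact Clopper-Pearson interval 27.7 to 6230), and had fractional counts in 3 libraries. Ccdc152 fell 9.79-fold, but its exons overlap those of Selenop on the opposite strand, and whether counting used strand is not given in the sources used here. By p-value, Adamts1 and Adamts5, 2 secreted metalloproteinases on chromosome 16, stood next to Clca3b, with falls of 3.17-fold and 3.58-fold. Among called genes with at least 5 CPM in the higher group, large rises belonged to Ngfr, the low-affinity nerve growth factor receptor, and to the epithelial transcription factor gene Bnc1, both from near the floor. Ngfr had 7 counts over the controls and 166 over the knockout libraries, a ratio of 23.8 (95% exact interval 11.3 to 60), and Bnc1 had 10 and 162, a ratio of 16.2 (8.6 to 34.5). Pde2a, a phosphodiesterase, rose 7.21-fold and the iodide transporter gene Slc5a5 7.03-fold. Crispld2 and the serine protease gene Htra3 rose 6.47-fold and 6.33-fold. Pnp2 rose 9.45-fold with fractional counts in all 6 libraries, so its value is uncertain. Ppic, a cyclophilin, rose 2.65-fold.

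Genes of G2 and mitosis were mostly lower. Of 30 members measured, 26 fell, 1 rose and 3 did not pass (adjusted over the list alone, 27 fell and 1 rose). The cytokinesis scaffold gene Anln fell 2.24-fold, the topoisomerase gene Top2a 1.74-fold and the centromere protein gene Cenpf 2.90-fold. Kif23, a motor of the central spindle, rose 1.71-fold. The list was lower than other genes (camera, adjusted p = 2e-09; adjusted p = 0.132 with an estimated correlation). Of 30 genes of S phase and DNA replication, 10 fell, 3 rose and 17 did not pass (adjusted over the list alone, 13 and 3), among them the replicative helicase genes Mcm6 and Mcm4, down 1.45-fold and 1.36-fold. That list did not pass by camera (adjusted p = 0.0799) and passed by fry, which tests against no change (adjusted p = 0.000484).

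Genes of the p53 and DNA damage response rose in 15 of 28 cases and fell in 4, with 9 not passing (adjusted over the list alone, 16 and 4). Mdm2, which targets p53 for degradation, and Ccng1 each rose 1.57-fold, and Gdf15 rose 1.43-fold, while the pro-apoptotic gene Pmaip1 fell 1.43-fold. The list test gave an adjusted p of 0.000899, and adjusted p = 0.132 with an estimated correlation. In the list of apoptosis, necroptosis and pyroptosis, 11 of 24 genes rose, 2 fell and 11 did not pass (adjusted over the list alone, 12 and 2). Casp8, the initiator caspase of death receptors, rose 1.83-fold and Bcl2l11 1.61-fold, and Casp12 fell 2.79-fold. Its adjusted p was 0.0302, and adjusted p = 0.242 with an estimated correlation. It lost the call with log2(TPM + 1) on filtered genes (adjusted p = 0.0521) and kept it in the other 2 TPM settings.

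Antioxidant genes regulated by NRF2, with genes of ferroptosis, included 12 that fell, 4 that rose and 7 that did not pass among 23 (adjusted over the list alone, also 12 and 4). The iron exporter gene Slc40a1 fell 3.12-fold, the glutathione synthesis gene Gclc 2.24-fold, Gsta4 3.93-fold and Srxn1 2.16-fold. The adjusted p was 3.97e-06, and adjusted p = 0.221 with an estimated correlation. Of 22 cholesterol biosynthesis genes, 11 fell, 1 rose and 10 did not pass (adjusted over the list alone, 12 and 1), by amounts such as 1.51-fold for Fdps and 1.27-fold for Hmgcs1. The list gave an adjusted p of 0.00536, and adjusted p = 0.132 with an estimated correlation.

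Markers of tubular injury and repair split. Of 26, 12 fell, 11 rose and 3 did not pass (adjusted over the list alone, also 12 and 11). The stem and progenitor surface marker Prom1 fell 3.08-fold, and the adhesion molecule gene Vcam1 fell 2.59-fold. Spp1, osteopontin, fell from 10700 ± 562 to 4350 ± 414 CPM. The list was called lower (adjusted p = 0.000343; adjusted p = 0.132 with an estimated correlation), with a median log2 fold change of only -0.02, and the call was lost with limma-voom (adjusted p = 0.208) and on TPM (adjusted p = 0.628). Among 15 keratins and genes of stratified epithelia, 8 rose, 3 fell and 4 did not pass (adjusted over the list alone, also 8 and 3). The simple-epithelium keratin genes Krt7 and Krt18 rose 1.87-fold and 1.64-fold, and Ly6a fell 1.68-fold. Its adjusted p was 0.0206, and adjusted p = 0.192 with an estimated correlation.

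Of 12 chemokine genes measured, 7 fell, 2 rose and 3 did not pass (adjusted over the list alone, also 7 and 2). Ccl20 fell 3.78-fold and Cxcl1 2.25-fold, and the membrane-bound chemokine Cx3cl1 rose 1.75-fold. The list gave an adjusted p of 0.025, adjusted p = 0.327 with an estimated correlation, and lost the call under DESeq2 (0.0735) and on TPM (0.133). Of 15 complement genes, 6 fell, 1 rose and 8 did not pass (adjusted over the list alone, 7 and 1), with the central component C3 down 3.68-fold and its regulator Cfi 2.06-fold. The complement list had an adjusted p of 0.0336, and adjusted p = 0.444 with an estimated correlation. It lost the call without control replicate 3 (0.0535) or without knockout replicate 2 (0.0515). Cytokines and inflammatory enzymes went both ways, with 6 of 18 higher, 5 lower and 7 not passing (adjusted over the list alone, 7 and 7). Lif rose 2.11-fold and Il33 fell 3.45-fold (list adjusted p = 0.151 by camera and 0.00567 by fry).

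Mesenchymal and matrix genes rose in 13 of 32 cases and fell in 2, with 17 not passing (adjusted over the list alone, 14 and 2). Sparc rose 1.72-fold, the fibrillin gene Fbn1 2.14-fold and Vim 1.32-fold, while the collagen gene Col5a2 fell 1.84-fold. The adjusted p was 0.00677, and adjusted p = 0.132 with an estimated correlation. Of 25 TGF-beta and YAP response genes, 14 rose, 4 fell and 7 did not pass (adjusted over the list alone, 14 and 5). The receptor tyrosine kinase gene Axl rose 2.01-fold, Ltbp2 2.44-fold and Id2 1.80-fold. That list gave an adjusted p of 0.000168, and adjusted p = 0.132 with an estimated correlation, and lost the call with log2(TPM + 1) on filtered genes (0.0521) but in neither of the other 2 TPM settings. Genes that earlier work links to ELF3 were split, with 6 of 20 higher, 7 lower and 7 not passing (adjusted over the list alone, 7 and 7). The list test called them lower (adjusted p = 0.0336; adjusted p = 0.242 with an estimated correlation), although the median was 0.03 and the mean -0.20. The call was lost with limma-voom (0.821), under DESeq2 (0.0735), on TPM (0.818), and without knockout replicate 1 (0.0847) or 2 (0.0515).

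**Figure D3:**
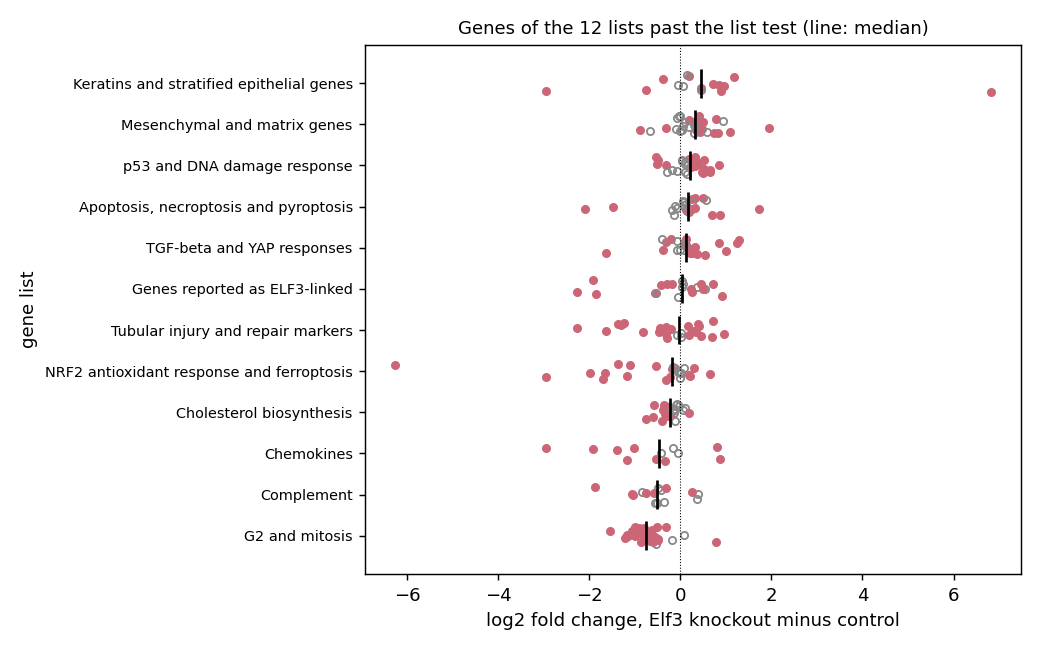
Log2 fold change of knockout over control for each measured gene of the 12 lists with a camera adjusted p under 0.05, 1 row per list and 1 point per gene. Filled points passed the threshold over all genes, open points did not, and the black line marks each list's median, at -0.74 for G2 and mitosis. The outermost points, Krt23 and Gsta1, chosen after their values were seen, rest on levels near 0 in 1 group.

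Lists of genes of the response to the 2 cytokines were not called against other genes by camera. By fry, which tests against no change, the type I interferon list (adjusted p = 0.000685) and the receptor and signalling list (0.0349) passed. Of 33 NF-κB and TNF response genes, 8 rose, 6 fell and 19 did not pass (adjusted over the list alone, 9 and 9; list adjusted p = 0.796). By p-value, the leading members were Vcam1, which fell 2.59-fold, Tnfaip2, which rose 1.89-fold, Nfkb1, which fell 1.33-fold, and Tnip1, which rose 1.42-fold. Of 25 IFNγ response genes, 5 rose, 7 fell and 13 did not pass (adjusted over the list alone, 5 and 8). The list adjusted p was 0.886. Gbp9 rose 2.18-fold and Irgm1 1.38-fold, while Gbp7 fell 2.11-fold and Parp14 1.31-fold. Gbp7 had fractional counts in 3 libraries, and exons of Gbp9 overlap those of Gbp8. Of the 33 listed genes, 21 had a mean under 5 CPM in the controls, which limits what this list can show. Type I interferon response genes included 3 that rose, 7 that fell and 12 that did not pass of 22 (adjusted over the list alone, also 3 and 7; 0.25), with Bst2 down 1.40-fold. Among 20 receptor and signalling genes for these cytokines, 5 rose, 4 fell and 11 did not pass (adjusted over the list alone, also 5 and 4; 0.702). The IFNγ receptor genes moved apart, Ifngr1 falling 1.66-fold and Ifngr2 rising 1.32-fold. For MHC class I presentation, 3 of 22 rose, 6 fell and 13 did not pass (adjusted over the list alone, also 3 and 6; 0.667), with the peptide transporter gene Tap2 down 1.54-fold. For MHC class II, 1 of 7 rose, 1 fell and 5 did not pass (adjusted over the list alone, also 1 and 1; 0.667), the protease gene Lgmn falling 1.47-fold.

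Nephron segment markers were not called as lists by camera. The count filter kept 13 of 31 proximal, 8 of 17 loop and distal and 9 of 20 collecting duct markers. Slc22a6, Kcnj1 and Aqp2, for example, averaged 0 counts in both groups, so the lists cover only detected markers. By fry, the 3 lists passed (adjusted p = 0.000685, 0.0295 and 0.00183 in that order). The epithelial junction (0.0185) and ETS family (0.0432) lists below also passed by fry. Of 13 proximal tubule genes, 3 rose, 6 fell and 4 did not pass (adjusted over the list alone, also 3 and 6; list adjusted p = 0.125). Keg1 fell 6.59-fold and the bicarbonate transporter gene Slc4a4 1.74-fold, and the water channel gene Aqp1 rose 3.14-fold. Of 8 loop of Henle and distal genes, 1 rose, 3 fell and 4 did not pass (adjusted over the list alone, 1 and 6; 0.299), with Cldn19 down 1.79-fold. Of 9 collecting duct genes, 3 rose, 3 fell and 3 did not pass (adjusted over the list alone, also 3 and 3; 0.125). Epithelial junction genes gave 12 higher, 13 lower and 17 not passing of 42 (adjusted over the list alone, also 12 and 13; 0.307). The tight junction gene Cldn1 fell 2.06-fold and the desmosomal gene Dsg2 1.54-fold. Of 17 ETS family genes, 5 rose, 3 fell and 9 did not pass (adjusted over the list alone, also 5 and 3; 0.667). Ehf, a close relative of Elf3, fell 2.22-fold, and Etv4 rose 1.80-fold.

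Markers of leukocytes, endothelium and podocytes were not called as lists by camera. By fry, the endothelial list passed (adjusted p = 0.000685), and the other 2 did not. With TMM scaling, none of 16 measured leukocyte markers passed, over all genes or adjusted over the list alone (list adjusted p = 0.886). Csf1r, the most abundant, stood at 23.4 ± 2.41 CPM in the controls and 19.5 ± 1.75 in the knockout (adjusted p = 0.0689), and was called lower only with library totals and with the GC and length offset. Of 6 endothelial markers, 2 rose and 4 did not pass (adjusted over the list alone, also 2; 0.151), among them Kdr, a VEGF receptor, up 5.59-fold from 1.45 CPM. Podocyte and parietal cell markers gave 3 higher, 4 lower and 3 not passing of 10 (adjusted over the list alone, also 3 and 4; 0.667), with Podxl up 2.30-fold.

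Of 25 glycolysis and hypoxia genes, 10 rose, 7 fell and 8 did not pass (adjusted over the list alone, 11 and 7; list adjusted p = 0.0783), with the glucose transporter gene Slc2a1 up 2.03-fold and Vegfa up 1.81-fold. Oxidative phosphorylation gave 4 higher, 7 lower and 17 not passing of 28 (adjusted over the list alone, also 4 and 7; 0.796), with Cox7a2 down 1.40-fold. For fatty acid oxidation and peroxisomes, 5 of 22 rose, 5 fell and 12 did not pass (adjusted over the list alone, also 5 and 5; 0.886), with Acadl down 1.46-fold. Of 22 genes of the unfolded protein and integrated stress response, 5 rose, 3 fell and 14 did not pass. Adjusted over the list alone, also 5 rose and 3 fell. Atf4 rose 1.32-fold, and the list adjusted p was 0.614 by camera. By fry, this list (adjusted p = 0.0295) and the glycolysis and hypoxia list (0.00367) passed. Of 33 ribosomal protein genes, 1 rose, 10 fell and 22 did not pass (adjusted over the list alone, 1 and 9; 0.125), Rplp1 falling 1.36-fold. Of 13 mitochondrially encoded genes, 2 fell and 11 did not pass (adjusted over the list alone, also 2; 0.264). Both that fell, mt-Co2 and mt-Atp6, had fractional counts in all 6 libraries, so their values are uncertain.

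All 12 list calls were made by camera with a preset correlation of 0.01 between genes, and 0 of 34 lists passed when camera estimated it. For 4 of the 12 (keratins, p53, cholesterol, mesenchymal and matrix) the estimate was below the preset value. A higher correlation therefore does not account for the loss of these 4 calls. For the p53 list, for example, the camera p rose from 0.000132 to 0.0126 although the estimate was lower. The 2 forms also differ in degrees of freedom, set by the libraries when the correlation is estimated and by the genes otherwise. How far this accounts for the loss was not tested, so 0 of 34 does not show that correlation between genes removes the calls. Labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, and Cre exposure cannot be told apart from Elf3 loss because both mark the same 3 libraries.

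Across 13638 genes, fold changes from estimated counts and from TPM correlated at r = 0.906, and genes are not independent replicates. Both came from the same libraries.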

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

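The GC and length offset was chosen after seeing the data; the other settings were fixed before the data were examined. Elf3 stayed lower and past the threshold under all 17 alternatives, at log2 fold changes of -3.11 to -2.45. On TPM fewer genes passed: 1421 higher and 1291 lower with log2(TPM + 1), 1412 and 1304 with log2(TPM + 0.1), and 1195 and 980 without a filter; the cause was not tested. By 2-fold or more, TPM gave 262 higher and 263 lower with a pseudocount of 1, and 236 and 241 without a filter, where the pseudocount by construction shrinks low genes. A mean of at least 5 CPM left 181 higher and 205 lower by 2-fold, with 11070 genes tested. Other counts stayed within 1.5 times. The number of lists past the threshold was 12, but 0 with an estimated correlation and 24 with fry, which asks another question. With the preset correlation, 6 of the 12 passed under every setting (keratins, mesenchymal and matrix, G2 and mitosis, p53, NRF2, cholesterol), and 2 lost the call with 1 library left out. Of 135 called named genes other than Elf3, 20 lost the call under at least 1 alternative, all 20 on TPM, and 0 with a library left out. No named gene or list reversed its sign while called. Single lists kept their side of the threshold in 537 of 574 list and setting combinations, fell short of it in 19 and passed it newly in 18, leaving aside the other set tests. Same-numbered libraries did not deviate together (r = 0.007, 0.003 and 0.003), and none correlated best with its own number. With the replicate block, 2561 genes were higher and 2585 lower, and no named gene or list lost its call. In the simulation, edgeR recovered 54.5% of 2-fold changes in genes under 5 CPM (6 of 11), against 97.4% at 5 CPM or more (38 of 39). Depth was not varied.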

Other observations

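In this part, the tests of leukocytes, of Cre and of IFNγ exposure were chosen after the results were seen, as were the present form of the receptor and kinase test and the gene family, neighbourhood and window tests and the genes named for them.

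Gene families that share a symbol stem, with at least 10 members tested, were compared in the same way as the lists. Of 166 families, 9 passed with the preset correlation, all 9 with an adjusted p of 0.48 or more with an estimated one. Keratin genes (Krt) rose in 8 of 11 cases and fell in 0 (adjusted p = 1.06e-06), where the 11 include the pseudogene Krt8-ps. TNF receptor superfamily genes (Tnfrsf) rose in 7 of 12 cases and fell in 0 (adjusted p = 0.00878), and interferon-inducible Ifi genes fell in 6 of 11 cases and rose in 0 (adjusted p = 0.0283), although the cytokine response lists were not called by camera. Adamts genes went both ways, with 5 of 14 higher, 4 lower and a median of 0.26 (adjusted p = 0.0117, direction of the call not recorded). Most members thus did not share the falls of Adamts1 and Adamts5. Both are members, so the call is not independent of their falls. Genes with the stem S rose in 7 of 14 cases and fell in 0 (adjusted p = 0.00878). This stem is not a gene family, since symbols cut at the first digit join genes such as S100a4 and S1pr3. Cyp genes fell in 8 of 18 cases and rose in 2 (adjusted p = 0.0422). Claudins, the sealing proteins of tight junctions, fell in 10 of 12 cases and rose in 1 (adjusted p = 2.81e-05), under all 3 scalings. Cldn2, the pore-forming claudin of the proximal tubule, went from 100.2 to 29.8 CPM and Cldn4 from 1380 to 1120 CPM, while Cldn23 rose. Wnt ligand genes rose in 7 of 10 cases and fell in 1 (adjusted p = 0.0141), with Wnt7a from 109.7 to 188 CPM and Wnt7b from 247 to 368 CPM, and Wnt5b falling from 7.52 to 2.63 CPM. Genes of the Hoxb cluster fell in 8 of 10 cases and rose in 1 (adjusted p = 0.0357), among them Hoxb2 from 108 to 77.1 CPM. The 8 include the opposite-strand transcripts Hoxb5os and Hoxb3os. Whether counting used strand is not given, and neighbours in a cluster are not independent.

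Within 5 Mb of Elf3, 40 of 91 tested genes were called, 44% against 36.5% elsewhere (Fisher's exact test, p = 0.156). Of 5 Mb windows, 2 held more genes changed 2-fold than the genome-wide share gives (adjusted p = 0.0149 each). On chromosome 5, from 85 to 90 Mb, all 7 of the 17 genes that changed fell, 4 of them Ugt2b paralogs. On chromosome 16, from 85 to 90 Mb, 6 of 13 changed, with Adamts1 and Adamts5 side by side. Neighbouring paralogs are not independent.

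Genes of G2 and mitosis fell in 26 of 30 cases, with Kif23 rising from 44.7 to 76.8 CPM while Racgap1, its partner in the centralspindlin complex, changed by -0.87 on the log2 scale. A bias of GC content or length is argued against, since with the offset the list's median stayed at -0.71, against -0.74 without it. Fewer leukocytes are argued against too, since their markers had a median of -0.012 (quartiles -0.25 and 0.18), although all tested except Csf1r lay under 10 CPM. Cre toxicity is neither favoured nor excluded. The p53 genes had a positive median of 0.216, but this was known when the test was chosen, so the test could not have failed. Cre and Elf3 loss cannot be told apart here because both mark the same libraries. Loss of Elf3 itself stays open as the biological hypothesis.

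mt-Co2 fell by 2.00 on the log2 scale, and mt-Co3 had an estimated count of 0.08 in 1 knockout library and 1787 in another. Each has a nuclear copy of 100% identity that took most of the reads. Summed with its copies, mt-Co2 was at -0.055 (SE 0.057) and mt-Co3 at -0.138 (SE 0.044, adjusted p = 0.014), and the value for mt-Co2 is consistent with reads being divided unevenly by the quantification. No biological explanation was tested for this pattern.

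IFNγ response genes were low for cells labelled as exposed to it, as a judgement without unexposed libraries for comparison. Of 33 listed genes, 21 had a mean under 5 CPM in the controls, Ido1 had 0 counts in all 6 libraries, and Cxcl9 averaged 1.33 counts in the controls. A lack of receptor or kinase transcripts is argued against, since the lowest of Ifngr1, Ifngr2, Jak1 and Jak2, which was Jak2, stood at 91.1 CPM. Weak or lapsed IFNγ exposure at harvest is neither favoured nor excluded. Of the 33 listed genes, 5 lay under 1 CPM in the controls, where the median was 2.95 CPM. Without unexposed libraries, no level here separates an absent from a weak response, so these counts cannot decide. Elf3 loss is not an explanation that covers the controls.

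The real split of the 6 libraries called 5028 genes and the highest of the other 9 splits 1. Each of those 9 mixes control and knockout libraries, so the difference between the groups becomes spread within them. Few calls there follow from this mixing, and the contrast is no support for the real split. With 10 splits, of which 1 gave as many genes, a share under 0.05 cannot be reached.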
